A study of Homo sapiens with 10 samples.

How the data were processed

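Ribosome profiling sequences the short pieces of mRNA that ribosomes protect from nuclease digestion, so a gene's value reflects its mRNA abundance and its translation together. It was done in 10 libraries of CFPAC-1 and PANC-1, established cell lines of human pancreatic ductal adenocarcinoma. Per the labels' protocols, cells received DMSO at 0.1% or imidazole ketone erastin (IKE), a derivative of the ferroptosis inducer erastin, and only cells that survived were collected after dead cells and debris had been removed. The treatment label gives 24 h of exposure, while the protocol for the footprint extract describes repeated treatment on consecutive days, so the exposure time is not settled here. Ribosomes were arrested with cycloheximide, lysates were digested with RNase I, and footprints were size-selected and depleted of rRNA before small RNA library preparation, per the labels' protocols.

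The deposited table holds 1 FPKM value per gene and library, per the file headers, that is fragments scaled by gene length and by the library's mapped fragments, rounded by the authors. The submitters' processing notes name fastp, Bowtie2 2.2.8, STAR, RSEM, DESeq2 and the GRCh38 build, with no role or order. The annotation, the strand setting and any filter on footprint length are not given in the sources used here, so values of overlapping or near-identical genes are uncertain. The authors' DESeq2 results are not used here. Every library is its own column, all 10 columns were matched to a library by name, and none was pooled.

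The table lists 20289 genes by Ensembl gene ID and pairs none of them with a name. The reference table of gene names used here matched 0 of them, so genes are given by ID alone, at most 2 higher and 2 lower for a comparison of 2 groups, and all called genes for the difference and the average of the IKE effects. For the same reason the 30 gene lists, the cell type markers and the individually fixed genes chosen before the data were examined were not tested here.

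The comparisons, the groups and the rule for named genes were fixed before the data were examined. A count-based test had been planned, with limma-trend on log2 values as the fixed fallback for normalized values; because the deposited values are FPKM, the fallback was used. Genes with a mean of at least 1 FPKM over the 10 libraries were tested (13125 genes). limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with the 4 groups in a single model (6 residual degrees of freedom), empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. All log2 fold changes below are on this scale, which understates changes of low values, and are given with standard errors. Of the called genes with a mean of at least 5 FPKM whose groups did not overlap, those with the largest changes were named; for the difference between the lines and for the joint effect, those with the smallest p were named. The rule asked for protein-coding genes, which IDs without names do not show. The average of both lines' effects as 1 contrast was added after the data had been seen.

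Depth was not stated with the values. In FPKM a gene's lowest values are multiples of what 1 read is worth, and these steps gave the relative depth of the libraries. The values of 646 of 1988 low genes (32.5%) came out as whole reads within 0.08 reads plus an allowance for the rounding of the FPKM. How many genes would pass this limit by chance was not measured. Reads were therefore not recovered for most genes, absolute depth stayed unknown and no count test was run. On 6000 simulated genes the relative depth was recovered with a largest error of 0.027%. Most simulated genes held whole reads, an easier case than the deposited values, so this error is not the accuracy of the depths given here. Replicate libraries differed by more than counting noise in every pair, with a variance of 3.33 to 7.98 times that noise. This rests on the 614 to 992 genes per pair with enough recovered reads and was not measured for the others. Log2 values correlated at 0.979 and 0.981 between CFPAC-1 replicates, 0.939 between PANC-1 DMSO replicates and 0.899 to 0.965 between PANC-1 IKE replicates. The labels call the replicates biological.

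The fit was tested on simulated data that kept each line's own spread, with 200 of 13125 genes changed. For CFPAC-1, 98 of 200 genes changed 4-fold were called, along with 4 unchanged genes. For PANC-1, 121 of 200 were called, along with 45 unchanged genes among 166 calls. At 8-fold, 164 genes in CFPAC-1 and 174 in PANC-1 were called, with 4 and 52 unchanged genes, and at 2-fold 0 and 5 were called, with 0 and 5 unchanged genes. The shared spread therefore gave PANC-1 p-values that were too small. Fits of the line's own groups called 2 unchanged genes among 73 calls at 4-fold in PANC-1 and 1 among 127 in CFPAC-1. The design fixed in advance was kept, and the results of the separate fits are given beside it.

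Alternatives covered the pseudocount, the filter, the scaling of the libraries, each library left out, a block on replicate numbers, separate fits, the overlap of the lines from separate fits, library weights, robust moderation and quantile normalization. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the depth estimate and the plots.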

Results

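Ribosome footprints were measured in surviving CFPAC-1 and PANC-1 cells after exposure to IKE, a compound of the erastin class that blocks cystine import and is used to induce ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. The series was set up to look for regulators of ferroptosis in pancreatic cancer. CFPAC-1 was represented by 2 DMSO libraries and 2 libraries with 10 µM IKE, and PANC-1 by 2 DMSO libraries and 4 libraries with 1 µM IKE. No dose was common to both lines. Genes are given by Ensembl ID because the values are not paired with gene names.

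Depth differed between the lines. Taking CFPAC-1 DMSO replicate 1 as 1.00, the other CFPAC-1 libraries had relative depths of 0.916 (DMSO replicate 2), 1.17 (IKE replicate 1) and 0.975 (IKE replicate 2). PANC-1 DMSO libraries had 0.508 and 0.328, and PANC-1 IKE replicates 1 to 4 had 0.877, 0.239, 0.5 and 0.211. For a gene of median length, 1 read was worth 0.115 FPKM in the deepest library and 0.641 FPKM in the shallowest. Between 12933 and 14424 genes were above 0. The median residual SD of log2 values was 0.18 in CFPAC-1 and 0.481 in PANC-1, and it was larger in PANC-1 for 87.7% of the genes.

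The most abundant genes held a larger share of summed FPKM in PANC-1 IKE replicates 2 to 4 than in the other libraries. IKE replicate 1 lay within the range of the CFPAC-1 libraries. Each library's own 10 genes were taken, so the genes can differ between libraries. The 10 most abundant genes of each library held 8.51% and 8.58% of summed FPKM in the PANC-1 DMSO libraries and 9.29%, 16.2%, 12.2% and 23.1% in IKE replicates 1 to 4, against 8.74% to 9.64% in the CFPAC-1 libraries.

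**Figure D1:**
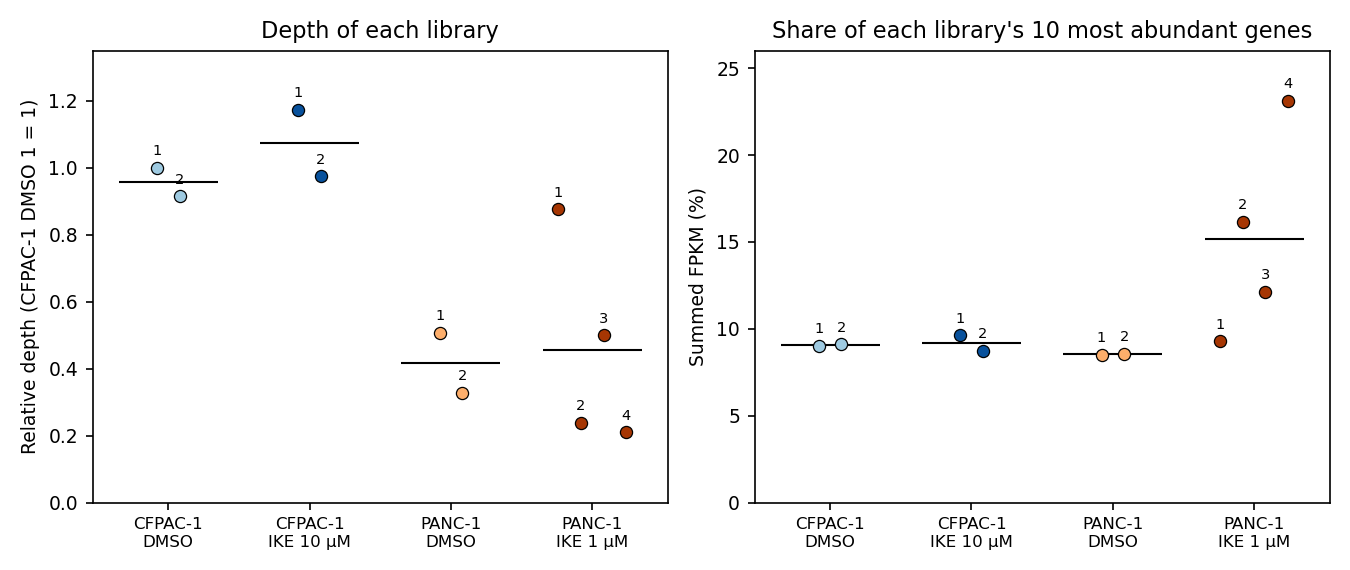
Relative depth (left, CFPAC-1 DMSO replicate 1 = 1) and percent of summed FPKM held by each library's 10 most abundant genes (right). Points are libraries labelled by replicate number and lines are group means; PANC-1 IKE replicates 2 and 4 had the lowest depths, 0.239 and 0.211, and the highest shares, 16.2% and 23.1%.

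The first comparison asked which genes changed their footprint level in CFPAC-1 with 10 µM IKE. ENSG00000128965 rose from 3.93 and 2.60 FPKM in the DMSO libraries to 63.0 and 75.9 FPKM in the IKE libraries, a log2 fold change of 4.06 ± 0.35 (SE; limma adjusted p = 0.00399), and was higher in 2 of 2 IKE libraries. It was the single gene called among 13125, and no gene was called lower. In the fit of the CFPAC-1 libraries alone, 16 of 12563 genes were called, all 16 higher in both IKE libraries, with log2 fold changes from 1.12 to 4.06 and a median of 1.78. The same separate fit on the 13125 genes of the shared model called 0 genes, with 1591 at p under 0.05, and gave ENSG00000128965 an adjusted p of 0.197, so the 16 calls rested on which genes entered. With library weights the adjusted p of this gene was 1.33e-05. In the shared model 194 genes had p under 0.05 where 656 were expected by chance. In the separate fit of CFPAC-1 the number was 1547. The residual SD was larger in PANC-1 for 87.7% of the genes, so the shared spread was too wide for most CFPAC-1 genes. Their p-values in the shared model were thus too large, and the few calls there are not evidence of a small response. IKE and DMSO values did not overlap for 42.6% of genes, where chance gives 33.3%. The call of ENSG00000128965 was lost without DMSO replicate 1 (adjusted p = 0.0503), DMSO replicate 2 (0.172) or IKE replicate 2 (0.228), where the remaining library of the group was assumed to vary like the other groups. There were 3 calls without IKE replicate 1 and 4 without PANC-1 IKE replicate 4.

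The second comparison asked the same in PANC-1 with 1 µM IKE. ENSG00000254806 fell from 19.6 and 22.7 FPKM in the DMSO libraries to being listed at 0 in 4 of 4 IKE libraries (limma adjusted p = 0.00477). ENSG00000268465 went the other way, from being listed at 0 in both DMSO libraries to 11.8, 7.29, 6.97 and 12.6 FPKM in IKE replicates 1 to 4 (limma adjusted p = 0.0442). No fold is given for these genes, since a group lay at 0. These 2 genes were the calls of this comparison, 1 higher and 1 lower. The call of ENSG00000268465 was lost in 8 of the 10 fits that left out a library, and the gene had an adjusted p of 0.0826 in the fit of PANC-1 alone. The separate fit called 2 genes, 1 higher and 1 lower, the lower being ENSG00000254806 (adjusted p = 0.0237). In the shared model the call of ENSG00000254806, though not its direction, was lost without DMSO replicate 1 (adjusted p = 0.0618) or DMSO replicate 2 (0.0828), and without IKE replicates 2 and 4 together (0.0528). It was also lost with library weights (0.186) and with the replicate block on replicates 1 and 2 (0.193). The comparison had 0 calls without either PANC-1 DMSO library, and 1 without PANC-1 IKE replicate 2 or 3 or without either CFPAC-1 IKE library.

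ENSG00000198712 was singled out after its values had been seen, as the most abundant gene of PANC-1 IKE replicate 4. Its level was 6887 and 10013 FPKM in the PANC-1 DMSO libraries and 26462, 66389, 47180 and 107524 FPKM in IKE replicates 1 to 4. The log2 fold change of 2.72 ± 0.48 did not pass the threshold (limma adjusted p = 0.0762), although the gene was higher in 4 of 4 IKE libraries. In CFPAC-1 it was at 168 and 232 FPKM with DMSO and at 468 and 444 FPKM with IKE. Its log2 fold change there was 1.203 ± 0.549 (limma adjusted p = 1 in the shared model).

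In PANC-1, 2304 genes had p under 0.05, 1051 higher and 1253 lower, against 656 expected by chance, and 78 had an adjusted p under 0.1. The fit of PANC-1 alone had 1398 of 12611 genes at p under 0.05. The first number is inflated by the shared spread, as the simulated data showed. The groups did not overlap for 22.4% of genes, where chance gives 13.3%.

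The third comparison asked whether genes moved the same way in both lines. No gene was called in both with limma, but the few calls in each line left little room for an overlap. At an unadjusted p under 0.05 in each line, 19 genes were higher in both, against 9.53 for independent lists, 4 were lower in both, against 7.16, 13 were higher in CFPAC-1 and lower in PANC-1, against 11.36, and 15 were lower in CFPAC-1 and higher in PANC-1, against 6.01. The lines share no libraries, but in this fit they share each gene's spread, so the lists are not independent. The overlap was therefore also taken from the separate fits of the lines, a choice made after the data had been seen, over 11512 genes in both. There 40 genes were higher in both, against 35.8 for independent lists, 27 were lower in both, against 43.1, 42 were lower in CFPAC-1 and higher in PANC-1, against 40.7, and 75 were higher in CFPAC-1 and lower in PANC-1, against 38. Fisher's exact test gave the last overlap an odds ratio of 2.24 (two-sided p = 1.21e-08), the genes lower in both 0.596 (two-sided p = 0.00727), the genes higher in both 1.13 (two-sided p = 0.478) and the remaining overlap 1.04 (two-sided p = 0.803), across genes, which are not independent replicates. The 2 kinds of fit thus placed the excess of opposite changes in different directions. Averaging the effects of both lines, a contrast added after the data had been seen, called 3 genes, all higher. ENSG00000092621 rose from 14.6 ± 0.9 (SD, n = 2) to 83.5 ± 4.9 FPKM (n = 2) in CFPAC-1 and from 23.7 ± 3.3 (n = 2) to 76.0 ± 22.5 FPKM (n = 4) in PANC-1. Its average log2 fold change was 2.02 ± 0.22 (SE; limma adjusted p = 0.0201). ENSG00000163993 rose from 143 ± 4.9 (SD, n = 2) to 477 ± 30 FPKM (n = 2) in CFPAC-1 and from 22.0 ± 3.3 (n = 2) to 47.7 ± 2.9 FPKM (n = 4) in PANC-1, an average of 1.41 ± 0.15 (SE; limma adjusted p = 0.0201). The third call was ENSG00000128965, with an average of 1.89 ± 0.23 (limma adjusted p = 0.0357), although its log2 fold change in PANC-1 was -0.29 ± 0.30, and this call was lost in 9 of the 10 fits that left out a library (adjusted p up to 0.379). Each of the calls of ENSG00000092621 and ENSG00000163993 was lost in 8 of the 10 fits that left out a library, with adjusted p up to 0.208.

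**Figure D2:**
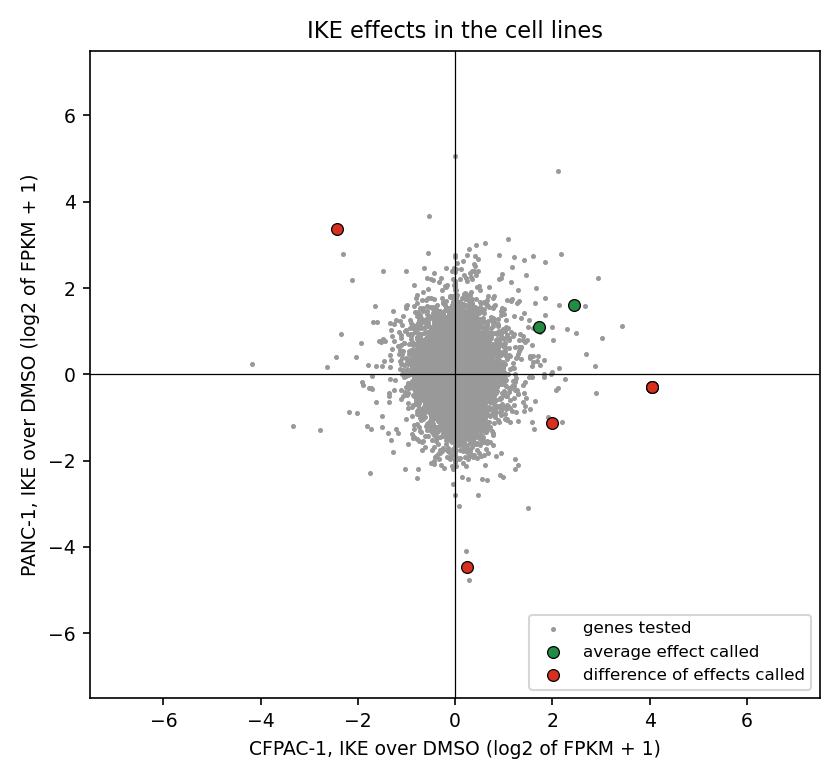
Log2 fold change of IKE over DMSO for the 13125 genes tested, in CFPAC-1 (horizontal) and PANC-1 (vertical), on the log2(FPKM + 1) scale. Green points are genes called for the average effect and red points the 4 genes called for the difference of effects, which cover ENSG00000128965, called for both; the cloud shows a correlation of -0.01.

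Across the 13125 genes the fold changes of the lines were uncorrelated, with a Pearson correlation of -0.01 and a Spearman correlation of -0.049, as a description across genes. Among the 6598 genes with a mean of at least 20 FPKM the values were -0.058 and -0.12. The median standard error of a log2 fold change was 0.415 in CFPAC-1 and 0.359 in PANC-1. Such noise weakens a correlation, and how far was not measured, so these values do not show that the responses are unrelated.

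The fourth comparison tested the difference of the IKE effects between the lines, in which line and dose change together. ENSG00000128965 had a log2 fold change of 4.06 ± 0.35 in CFPAC-1 and -0.29 ± 0.30 in PANC-1, a difference of -4.34 ± 0.46 (SE; limma adjusted p = 0.015), a call lost in 6 of the 10 fits that left out a library (adjusted p up to 0.318). ENSG00000103257 went from 17.9 ± 0.3 (SD, n = 2) to 73.9 ± 0.7 FPKM (n = 2) in CFPAC-1 and from 204 ± 44 (n = 2) to 92.6 ± 18.6 FPKM (n = 4) in PANC-1. Neither of its effects was called in the shared model (limma adjusted p = 0.142 and 0.118), the separate fit of CFPAC-1 called its rise there (limma adjusted p = 0.0129), and the difference was -3.12 ± 0.39 (SE; limma adjusted p = 0.0374), a call lost in 9 of the 10 fits that left out a library (adjusted p up to 0.378). ENSG00000268465 was at 8.29 and 3.39 FPKM in the CFPAC-1 DMSO libraries and at 0 and 0.42 FPKM in the IKE libraries, opposite to its direction in PANC-1 (limma adjusted p = 0.015; lost in 7 of the 10 such fits). ENSG00000254806 was at 5.27 and 13.1 FPKM with DMSO and 7.09 and 14.2 FPKM with IKE in CFPAC-1, while it fell in PANC-1 (limma adjusted p = 0.0374), and the call of this difference was lost in all 10 such fits (adjusted p from 0.0695 to 0.378). These 4 genes were all the calls, 1 higher and 3 lower in PANC-1 relative to CFPAC-1, and 1104 genes had p under 0.05. Leaving out either PANC-1 DMSO library or any 1 of the CFPAC-1 libraries left 0 calls. Without PANC-1 IKE replicate 1 there was 1 call, and without replicate 2 or replicate 3 there were 2.

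**Figure D3:**
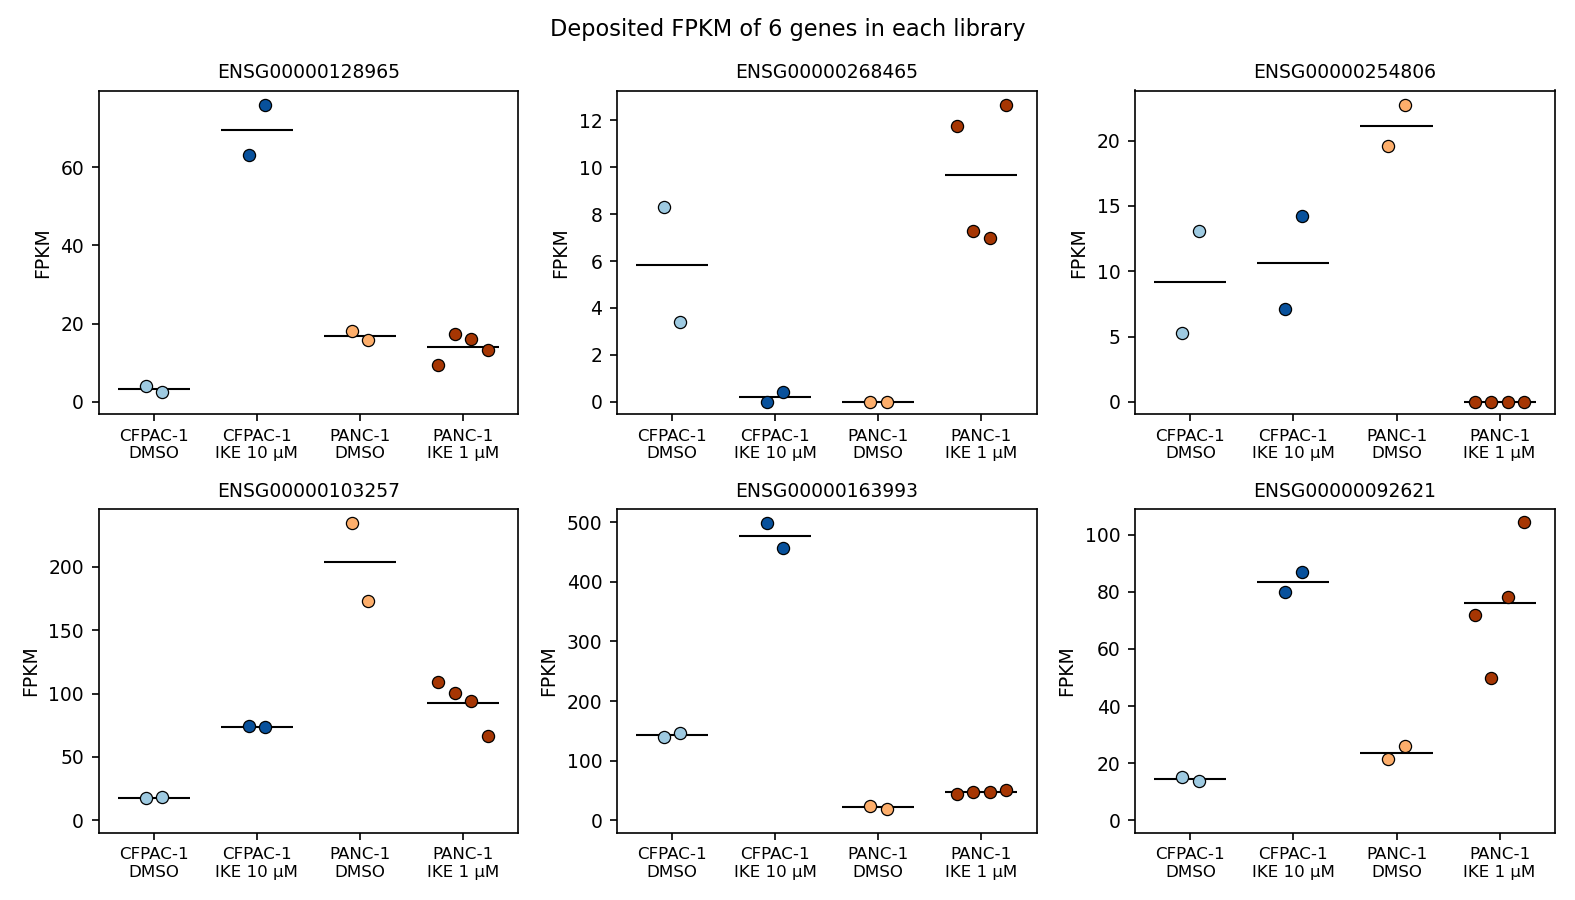
Deposited FPKM of 6 genes in each library, by group; points are libraries and lines are group means. ENSG00000128965 lay at 63.0 and 75.9 FPKM in CFPAC-1 with IKE and between 9.38 and 18.0 FPKM in PANC-1, and ENSG00000254806 was at 0 in the 4 PANC-1 IKE libraries.

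The baseline comparison set PANC-1 against CFPAC-1 in DMSO. ENSG00000108691 was at 2147 and 1134 FPKM in PANC-1 and at 0 and 1.64 FPKM in CFPAC-1, a log2 difference of 9.91 ± 0.50 (SE; limma adjusted p = 1.32e-06). ENSG00000087245 was at 857 and 806 FPKM in PANC-1 and at 0.46 and 0 FPKM in CFPAC-1, a difference of 9.43 ± 0.31 (limma adjusted p = 3.1e-07). ENSG00000164825 was at 3426 and 3683 FPKM in CFPAC-1 and at 5.69 and 0 FPKM in PANC-1, a difference of -10.42 ± 1.52 (limma adjusted p = 0.000516). ENSG00000165949 was at 3716 and 4605 FPKM in CFPAC-1 and at 8.74 and 0 FPKM in PANC-1, a difference of -10.37 ± 1.63 (limma adjusted p = 0.000825). The size of these 4 differences depends on the pseudocount, since 1 line lay at or near 0, while the calls and directions held in all 24 alternatives. The directions were largely fixed by naming only genes whose groups did not overlap. With pseudocounts of 0.1 and 5 the differences were 11.87 and 8.09 for ENSG00000108691, 11.78 and 7.32 for ENSG00000087245, -12.19 and -8.93 for ENSG00000164825, and -12.10 and -8.965 for ENSG00000165949. Without PANC-1 DMSO replicate 1 or 2 the difference was -11.795 or -9.05 for ENSG00000164825 and -12.015 or -8.73 for ENSG00000165949. Over 26 genes chosen for at least 200 FPKM in every CFPAC-1 library and 0 in PANC-1 DMSO replicate 2, the summed level in the other PANC-1 libraries was 0.002% to 0.87% of that in CFPAC-1, with 0.213% in DMSO replicate 1. In all, 4410 genes were called, 1984 higher and 2426 lower in PANC-1, and 4201 of them differed at least 2-fold. Quantile normalization turned the balance of directions, with 2354 higher and 2170 lower. Values of the lines did not overlap for 70.6% of genes, where chance gives 33.3%. With at least 10 FPKM in both DMSO libraries of a line, 47 PANC-1 genes were listed at 0 in both CFPAC-1 DMSO libraries and 125 CFPAC-1 genes at 0 in both PANC-1 DMSO libraries. A value of 0 comes more easily in the shallower PANC-1 libraries, so these counts are not directly comparable. Without CFPAC-1 DMSO replicate 1 the calls numbered 2495, and without replicate 2 they numbered 2519.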

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

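All tests of explanations in this part were chosen after the results had been seen.

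ENSG00000164825 and ENSG00000165949, abundant in CFPAC-1, stood apart in PANC-1 IKE replicate 4, at 41.1 and 45.6 FPKM against 0 to 3.29 and 0 to 6.66 FPKM in the other 3 IKE libraries; of 20 values checked in this way 2 stood apart, and chance gives about 1 in 20. Over 26 genes with at least 200 FPKM in every CFPAC-1 library and 0 in PANC-1 DMSO replicate 2, the summed level was 0.87% of that in CFPAC-1 in IKE replicate 4, 0.163%, 0.002% and 0.019% in IKE replicates 1 to 3, and 0.213% in DMSO replicate 1. Whether the 26 genes rose with IKE in PANC-1 as a whole cannot be decided. DMSO replicate 2 was at 0 by the choice of the genes, so the comparison rests on DMSO replicate 1. Of the 4 IKE libraries, 1 lay above that library. CFPAC-1 material in IKE replicate 4 is a candidate source. Across the 26 genes the FPKM of IKE replicate 4 followed the CFPAC-1 mean (Spearman correlation 0.849, 24 genes above 0). The CFPAC-1 mean was also followed at lower levels in IKE replicate 1 (0.769, 25 genes) and DMSO replicate 1 (0.762, 22 genes). A response of the cells in IKE replicate 4 alone was not tested.

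The 10 most abundant genes of PANC-1 IKE replicate 4 held 7.02%, 15.9%, 11.1% and 23.1% of summed FPKM in PANC-1 IKE replicates 1 to 4, against 5.83% and 7% in the DMSO libraries and 1.39% ± 0.07 (SD, n = 2) in CFPAC-1 DMSO. Fewer reads by themselves are argued against as a cause, since FPKM is scaled by the library's mapped fragments. For a gene of median length 1 read was worth 0.564 FPKM in IKE replicate 2 and 0.641 FPKM in IKE replicate 4. There these 10 genes held 15.9% and 23.1% of 1364966 and 1289986 summed FPKM, far more than such steps. Something else that goes with low depth stays open, and the ranking by depth does not settle it. The IKE libraries ranked in the opposite order by depth, an association among 4 libraries. At like depth, PANC-1 DMSO replicate 1 (0.508) held 8.51% in its own 10 most abundant genes and IKE replicate 3 (0.5) held 12.2%. With each library's own 10 most abundant genes, the DMSO libraries lay below the line of share on depth through the 4 IKE libraries (log2 deviations of -0.53 and -0.87), but inside its 95% prediction intervals of 5.99% to 25.2% and 7.73% to 31.8%. IKE exposure stays open too: the exact two-sided permutation p was 0.2, the smallest that 2 against 4 libraries allow is 0.0667, and the genes had been picked from an IKE library.

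The IKE effect on ENSG00000128965 differed between the lines by -4.34 on the log2 scale. Low depth in PANC-1 is argued against, since in the fit of PANC-1 alone, with that line's own spread, the upper 95% limit of its log2 fold change was 0.54, against 4.06 ± 0.35 (SE) in CFPAC-1. A PANC-1 level already as high as in treated CFPAC-1 is argued against too, since the lowest CFPAC-1 IKE value was 3.51 times the highest PANC-1 DMSO value. The starting levels did differ. In DMSO the gene was higher in PANC-1 than in CFPAC-1, by 2.08 ± 0.35 on the log2 scale (SE; limma adjusted p = 0.0012). Whether this higher start limited a further rise was not tested. The lower dose given to PANC-1 and the line itself cannot be told apart, because CFPAC-1 received 10 times the dose and no dose was given to both.

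The difference test also called ENSG00000103257, with a PANC-1 minus CFPAC-1 difference of -3.12 on the log2(FPKM + 1) scale, a call lost in 9 of the 10 fits that left out a library (adjusted p up to 0.378). ENSG00000268465 and ENSG00000254806 were called too, at fitted values of 5.79 and -4.70 that are set by the pseudocount and are not sizes of change, because each has a group at 0. For ENSG00000268465 the fitted value was 11.13 with a pseudocount of 0.1 (limma adjusted p = 0.0188) and 2.55 with 5, where the call was lost (limma adjusted p = 0.111).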

How the results depend on the processing

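The separate fit on the genes of the shared fit, library weights, robust moderation, quantile normalization, the fits without PANC-1 IKE replicates 2 and 4 or with replicates 1 and 2 only, the overlap from separate fits and the average effect were chosen after seeing the data, and their results had been seen when they were listed. Count-based tests, voom and the gene list tests were not run, because the values are FPKM without names. The calls with IKE were few and moved with many choices. Named genes kept their direction under every alternative run, in the comparisons they were named or called for. For genes named because their groups did not overlap, this was largely built in by that choice and is no sign of robustness. Shallow PANC-1 libraries limit low genes.

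For CFPAC-1 (1 call), a pseudocount of 0.1 gave 2 calls, no filter 4, scaling without genes over 1% of a library 2, the separate fit 16, the separate fit on the genes of the shared fit 0, library weights 54 (38 higher, 16 lower) and the fit without PANC-1 IKE replicates 2 and 4 gave 2. Leaving out 1 library gave 0 to 4. For PANC-1 (2 calls), pseudocounts of 0.1 and 5 gave 5 and 1, no filter 7, scaling without genes over 1% 1, the separate fit on the genes of the shared fit 1, library weights 0, the fit without IKE replicates 2 and 4 1, replicates 1 and 2 unpaired 4, and leaving out 1 library 0 to 3. For the difference (4 calls), a pseudocount of 5 gave 1, no filter 2, the fit without IKE replicates 2 and 4 1, replicates 1 and 2 unpaired 1, and leaving out 1 library 0 to 4. For the average effect (3 calls), a pseudocount of 0.1 gave 5, no filter 1, library weights 6, replicates 1 and 2 unpaired 1, and leaving out 1 library 0 to 3. The baseline count (4410; 1984 higher, 2426 lower) was 4524 with quantile normalization (2354 higher, 2170 lower) and ranged from 2495 to 5308 with 1 library left out. Calls in both lines stayed at 0 in all 24 alternatives. With so few calls in at least 1 of the lines an overlap was hardly possible, so this 0 does not show that the lines respond differently. The correlation between the lines was 0.008 with a pseudocount of 0.1, -0.047 without PANC-1 IKE replicates 2 and 4, and -0.044 to 0.027 with 1 library left out. Fits that leave out libraries have fewer samples; for the other changes the cause was not tested.

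Replicate numbers were not established as pairs: deviations of same-numbered libraries correlated at 0.049 in CFPAC-1 and at -0.169 and -0.163 in PANC-1. With the replicate block on replicates 1 and 2, 0 genes were called in CFPAC-1, 0 in PANC-1, 0 for the difference, 0 for the average effect and 2546 at baseline.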

Other observations

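In the separate fit of CFPAC-1, 16 genes were called, all higher with IKE. In PANC-1, 10 of them had a higher mean with IKE, 4 were higher at p under 0.05 in the shared fit and 1 was lower. Over all 13125 genes of that fit, 1051 were higher and 1253 lower at this limit. Its PANC-1 p-values were too small, and it shares the spread of CFPAC-1, the line in which the 16 genes were picked. With library weights, 15 of the 16 were called as well. The weights came from the same libraries and were 2.3 to 2.47 for CFPAC-1 and 0.205 to 1.87 for PANC-1, so this is not independent support. On the genes of the shared model the separate fit called 0.

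The 10 most abundant genes of PANC-1 IKE replicate 4 were picked from a library that counts in the IKE mean, so higher IKE values are partly built in. All 10 had a higher mean with IKE in PANC-1, with log2 fold changes from 0.02 to 2.72 and a median of 0.90. For 4 of them every IKE library lay above every DMSO library. Over all genes tested, the groups did not overlap, in either direction, for 22.4%. None of the 10 was called with limma (smallest adjusted p = 0.0762). In CFPAC-1 their median log2 fold change was 0.87.

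ENSG00000087245, named for its baseline difference, was at 857 and 806 FPKM in PANC-1 DMSO and at 389, 356, 264 and 333 FPKM with IKE, a log2 fold change of -1.32 ± 0.27 that did not pass the threshold (limma adjusted p = 0.0999) although it was lower in 4 of 4 libraries.

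Over all libraries, 44 genes were listed at 0 in the 6 PANC-1 libraries with at least 10 FPKM in each of the 4 CFPAC-1 libraries, and 7 the other way round. These counts are not directly comparable. A value of 0 comes more easily at the PANC-1 depths of 0.211 to 0.877 than at the CFPAC-1 depths of 0.916 to 1.17. The reverse rule also asked for 10 FPKM in 6 libraries and not in 4.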
